A study of Homo sapiens with 12 samples.

How the data were processed

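T-HESC cells, human endometrial stromal fibroblasts immortalised with telomerase, received 50 nM of an siRNA against TUB or a control oligonucleotide. Per the labels, cells were plated 18 h before transfection, transfected for 6 h and harvested at 48 h. The submitters kept knockdowns of over 70% by quantitative PCR against GAPDH. Per the labels, strand-specific libraries of total RNA depleted of ribosomal RNA were sequenced in single-end reads of 50 nt, and each of the 3 biological replicates of a group is listed as 2 runs, a and b. The labels therefore list 12 samples, 6 per group. Both runs of TUB siRNA replicate 1 are labelled as not used by the submitters.

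The deposited file is the authors' comparison of TUB siRNA with control siRNA, 1 row per transcript, and it holds no values per library. The processing notes of the submitters name HISAT2 2.1.0, StringTie 1.3.6, edgeR, limma, DESeq2 2.11.40.6 and the genome build hg38, without a role, an order or an annotation release. Per the file headers, the authors give a signal per transcript, the base mean, which is the mean over all fitted libraries of read counts divided by size factors. The authors also give the log2 fold change of each transcript and its standard error, both on a log2 scale. A deposited score per transcript, the Wald statistic, is the log2 fold change divided by the standard error. The deposited p-value of each transcript is two-sided, and the authors' adjusted p-value is by the method of Benjamini and Hochberg. Recomputed from the deposited p-values, the adjusted p differed by at most 6.16e-15. Positive log2 values mean a higher level with TUB siRNA.

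The depth per sample is unknown, since counts per sample were not analysed here. The number of fitted libraries was read from the lowest base means, each of which is 1 read in 1 library divided by its size factor and by the number of libraries. At a tolerance of 1 in 1000 there were 5 such values, 3 on the control side of the contrast and 2 on the TUB siRNA side by the sign of their log2 fold change. This is the number given by 3 control replicates and 2 TUB siRNA replicates with their runs pooled. Relative size factors ran from 0.896 to 1.09. None of the 5 libraries can be matched to a named sample. Precision comes only from the authors' standard errors, whose median was 0.343 over the transcripts with a base mean of at least 100. These errors cover the variation between so few libraries as the authors modelled it, and no SD or interval per group was computed.

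Transcript identifiers were matched, with the version dropped, to GENCODE release 29 on GRCh38, which gave symbols, coordinates, exons and 3′ UTRs. Of all identifiers 82.6% matched, and of the tested ones 93.6%, which is 23701 matched and 1617 unmatched. Unmatched transcripts entered the count of calls and no other result. A transcript was called when the authors' adjusted p was under 0.05. A further 804 transcripts with counts had no p-value and were not called, with base means from 60.9 to 7992. Another 8440 transcripts had a p-value and no adjusted p, and their base means did not exceed 1.86.

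Gene sums were made after the data had been seen, because the table turned out to list transcripts. The control and TUB siRNA levels of each transcript were solved from the base mean, the log2 fold change and the 3 and 2 libraries per side, and added over the matched transcripts of a gene. The standard error of the log2 ratio of the sums was propagated by the delta method, as if the transcripts of a gene were independent. Two-sided normal p-values were adjusted by Benjamini and Hochberg over the 12674 genes with a summed base mean of at least 10. Reads assigned to 1 transcript are lost to another, which makes their errors dependent, so these p-values are approximate, and the robust spread of the gene-sum statistics was 0.559 where 1 is the theoretical value.

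Gene lists, 40 in all, were tested with cameraPR of limma 3.58.1 under R 4.3.3, two-sided, on the authors' Wald statistic with a preset correlation of 0.01. Each gene entered with its transcript of the highest base mean, and the 37 lists with at least 5 measured members were adjusted together. An estimated correlation needs values per library, so no such test could be run. Beside each test stand the numbers of members past the threshold over all transcripts and adjusted over the list alone.

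For the sequences in 3′ UTRs, every heptamer found in at least 100 genes was tested in a weighted regression of the gene-sum change on its presence. The 3′ UTR was that of the transcript of the highest base mean, of at least 50 nt, in genes with a summed base mean of at least 100. Changes were limited to 1 on the log2 scale, weights were the inverse of the squared standard error plus 0.05, and UTR length and GC content with their squares were covariates. This search, and the classes of sites drawn from it, came after the data had been seen. Genes are not independent replicates, so its t is a ranking of sequences and not a test across samples.

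Base means up to 100 were also solved into whole counts in the 5 unnamed libraries, with 1 solution for 100% of 22720 transcripts. Log2 fold changes from these counts differed from the deposited ones by a median of 0.00455 over 1837 transcripts with a small standard error. They were used only for the number of transcripts absent from some libraries and for the direction of called ones. Sharing of 50-nt sequence between transcripts and genes was counted over all windows of each named transcript. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, sympy 1.14.0 and matplotlib 3.10.9.

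The contrast, the threshold, the gene lists and the rule for named genes were fixed before the data were examined. The rule names TUB and the tubby-like genes, the 12 highest and the 12 lowest log2 fold changes among called transcripts with a base mean of at least 100 and a gene symbol, the 5 smallest p-values in each direction, up to 4 called members of each list and up to 2 that were not called, and in every case PRL, IGFBP1 and GAPDH. The gene sums, the partner transcripts and the heptamer were named after their values were seen. Alternatives tried include other filters and thresholds, other nulls, enlarged standard errors, another centring, gene sums in place of transcripts and other settings of the list test.

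The procedures were tested on simulated data. With 200 of 12674 gene sums changed, 26% of 50 abundant genes were recovered at 1.5-fold, 58% at 2-fold, 86% at 4-fold and 70% at 8-fold, and 5 of 125 called genes were unchanged ones. Here transcripts were drawn independently with the deposited standard errors, and all transcripts of a changed gene moved together. Reads lost from 1 transcript to another were not simulated, so these rates do not cover that dependence. A heptamer planted with a shift of −0.1 ranked 1 in 10 of 10 runs, and with no shift the largest absolute t was 6.00. Counts were solved correctly for 100% of 4001 simulated transcripts. Of 5 lists of 25 genes shifted by 0.5 in the Wald statistic 4 were called, of 25 unshifted lists 0. These statistics were independent normal draws without the extreme values of the deposited Wald statistics, so this rate does not carry over to the real lists. In the data, the 24 genes of cholesterol synthesis had a mean Wald statistic of −0.774 and did not pass (cameraPR, adjusted p 0.0666). A list that did not pass therefore does not exclude a shift of 0.5. Left out were the raw reads, which were not available, and the samples labelled as not used, which the table does not hold.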

Results

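RNA was measured in T-HESC, a line of human endometrial stromal fibroblasts immortalised with telomerase, 48 h after transfection with an siRNA against TUB or with a control oligonucleotide. TUB encodes tubby, a protein that binds phosphoinositides at the plasma membrane and carries receptors into the primary cilium. The labels list 12 samples, 6 per group, as 3 biological replicates with 2 runs each, and mark both runs of TUB siRNA replicate 1 as unused. Values come from the authors' deposited table, which compares TUB siRNA with control siRNA for each transcript. It gives the mean normalised read count over all libraries, called base mean here, a log2 fold change with its standard error (SE), and an adjusted p-value. Counts per library are not in that table, so the depth of each sample is unknown and no value of a named replicate can be given. Its lowest base means point to 5 libraries, 3 on the control side and 2 on the TUB siRNA side. The base means of the authors' deposited table add up to 15924129 reads per library. Of 100454 transcripts listed, 34562 had reads and 25318 had an adjusted p, with a median base mean of 65.9.

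The comparison asks which RNAs of endometrial stromal cells depend on TUB, in a series on how decidualization, the change of stromal cells for pregnancy, evolved. TUB RNA itself stood at 53.9 normalised reads with TUB siRNA against 229 with control. Its only matched transcript with reads, TUB-202 (ENSG00000166402; GRCh38, chr11:8038633–8106112, plus strand, 13 exons), had a log2 fold change of −2.09 (SE 0.671, base mean 159). In the authors' deposited table its adjusted p was 0.0752, so the change did not pass the threshold of 0.05 over all transcripts. Among the tubby-like genes, adjusted over the list alone, 1 of 3 members was lower, and that was TUB. TULP3-202 stood at −0.05 (SE 0.237) and TULP4-202 at −0.14 (SE 0.236), while TULP1 and TULP2 were not tested.

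Most of the called transcripts belonged to genes whose summed level changed by less than 1.5-fold, although many of these sums had large errors. XPO6, TCEAL9, PSME1 and RPL21 were among the 57 genes with 1 transcript higher and another lower. Summed over transcripts, CASP3, SPTLC1, OSTM1 and NEDD4 were among the genes that fell, and RASSF2, NTN4 and AGO2 among those that rose. For CASP3, OSTM1, RASSF2 and AGO2 the sum held 1 transcript and is that transcript's own value. Of the sums that fell, 14 of 33 with a searched 3′ UTR held the sequence AATAGTA there, against 12.1% of all gene sums. AATAGTA was itself picked by a search over the changes of these gene sums. Lists of decidual, ciliary and cell-cycle genes held no shift that passed, and the only list that did, the RNAs encoded by mitochondria, did not pass without MT-ATP6.

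At an adjusted p under 0.05 in the authors' deposited table, 569 transcripts of 25318 were called (2.25%), 246 higher and 323 lower. They belonged to 459 named genes, and 57 of these (12.4%) had transcripts called in both directions. The median absolute log2 fold change of the called transcripts was 6.19, and 368 of them (64.7%) were at 5 or beyond. Of the 539 called transcripts matched to a gene, 427 (79.2%) were in genes whose summed level changed by less than 1.5-fold. Another 98 (18.2%) were in genes that changed at least 1.5-fold in the same direction. Both numbers include genes whose sum holds 1 transcript, such as AGO2 among the 427 and MT-ATP6 among the 98. There the sum is the transcript's own value, so it cannot differ from the transcript. For the 165 called transcripts with a base mean of 20 to 100, counts in the unnamed libraries could be solved, and in all 165 both TUB siRNA libraries lay beyond the 3 control libraries. These transcripts were called on the same libraries, so this separation follows largely from the call and is no separate check. Of the 165, 105 had 0 reads in some libraries and at least 10 in each of the others. Over all transcripts of these base means, called or not, 107 of that kind followed the real split of the 5 libraries. The other splits of 2 against 3 held a median of 107. For more abundant ones the number of libraries that share a direction cannot be given.

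Several of the smallest p-values in the authors' deposited table belonged to pairs of transcripts of 1 gene. XPO6, which encodes an exportin for actin, had XPO6-208 (chr16:28097979–28211550, minus strand) at −8.19 (SE 0.440, adjusted p 1.23e-73) and XPO6-201 (chr16:28097995–28211869) at +12.59, while the sum of its transcripts changed by +0.22 (SE 0.979). TCEAL9, a small elongation-factor-like gene, had TCEAL9-202 (chrX:103356501–103358462, plus strand) at +3.09 (SE 0.172, adjusted p 1.04e-68) and TCEAL9-201 (chrX:103356489–103358195) at −3.24 (SE 0.204, adjusted p 4.54e-53). Its summed level was 2324 with control and 2265 with TUB siRNA, a log2 change of −0.04 (SE 0.134). PDHB, a subunit of pyruvate dehydrogenase, had PDHB-201 (chr3:58427630–58433852, minus strand) at −2.15 (SE 0.109, adjusted p 1.54e-82) and PDHB-206 at +10.95, with a gene sum of −0.72 (SE 0.578). G3BP1-202 (chr5:151771910–151812785, plus strand), from the stress-granule gene G3BP1, was at +8.98 (SE 0.433, adjusted p 2.39e-91) beside a gene sum of −0.01 (SE 1.36). CYTH3-201 (chr7:6161776–6272644, minus strand), from an exchange factor for ARF GTPases, was at −6.32 (SE 0.305, adjusted p 2.39e-91) beside a sum of −0.30 (SE 1.67). CMTR2-201 at +4.92 (SE 0.367), ZBTB7B-203 at +7.31 (SE 0.607), FOSL2-202 at +3.43 (SE 0.286) and YY1AP1-210 at −4.20 (SE 0.300) complete the 5 smallest in each direction, and their gene sums lay between −0.69 and +0.27. Part of YY1AP1-210 (37.5% of its 50-nt windows) is also found in GON4L, so its value is uncertain.

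The highest log2 fold changes among abundant transcripts in the authors' deposited table were those of XPO6-201, RDH11-203 (+12.38), LIMS1-215 (+12.37), SYNCRIP-201 (+12.04), NME4-201 (+11.98), EIF5-202 (+11.67), RPL21-202 (+11.14), PSME1-205 (+11.08), PDHB-206, TLK2-203 (+10.81), NDUFB1-207 (+10.80) and GABARAPL1-201 (+10.80). The lowest were those of PRKAR1A-201 (−13.10), RPL21-203 (−10.70), FAM107B-229 (−10.66), B4GALT4-201 (−10.62), RAP1GDS1-205 (−10.60), SENP1-204 (−10.45), ADM-208 (−10.45), MAPRE2-201 (−10.37), PPP3CB-203 (−10.35), ZFP90-209 (−10.34), ZNF518A-210 (−10.28) and SMIM30-204 (−10.23). A level near 0 in 1 arm sets the size of these values, so they are no measure of the size of a change. Summed over transcripts, the same genes stood between −1.17 (ZFP90, SE 1.69) and +1.13 (LIMS1, SE 1.38), and none of the sums passed. Of the 34 transcripts named for their size or p-value, 21 had another transcript of the gene called in the other direction, such as PSME1-201 at −10.04 and MAPRE2-203 at +10.43. The other 13, among them those of EIF5, NME4, ADM and SMIM30, had none. RPL21-202 and RPL21-203 share 57.4% and 58.1% of their windows with other genes, mainly the pseudogene RPL21P16, and TLK2-203 shares 55.5% with TLK2P1, so these are uncertain. Smaller shares hold for RDH11-203 (15.8%), PRKAR1A-201 (14.4%) and LIMS1-215 (13.8%). Over the 34 named transcripts, a median of 98.2% of windows are held by other transcripts of the same gene. For most of them, few windows are therefore found in that transcript alone. Every annotated transcript of the gene was counted, with reads or without, so the share held by the partner transcript alone can be lower. The lowest share was 26.9%, that of G3BP1-202.

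**Figure D1:**
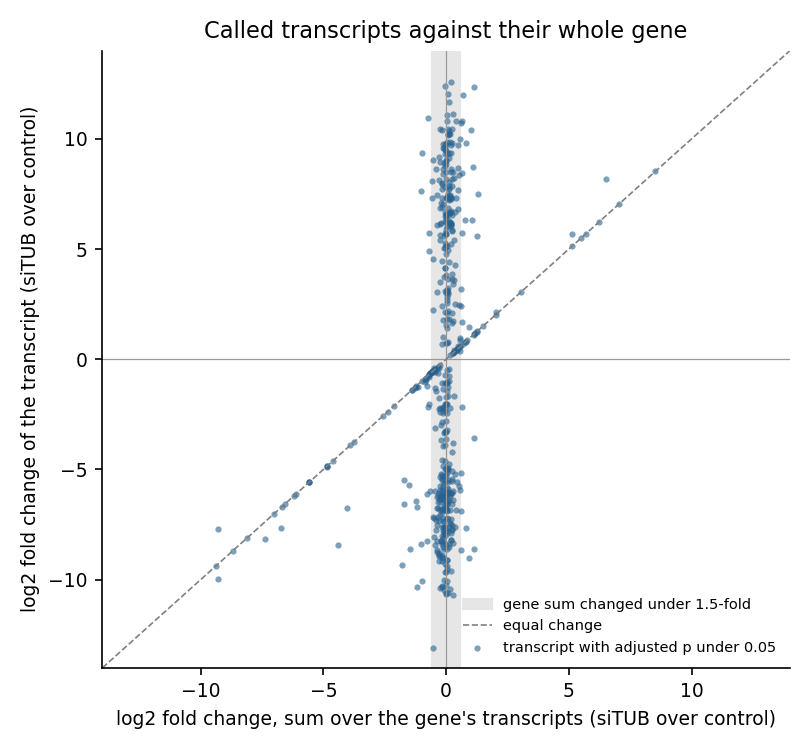
Each point is a called transcript, with its log2 fold change on the vertical axis and that of the sum over its gene's transcripts on the horizontal axis, both TUB siRNA over control. Of the 539 points, 427 lie in the grey band where the gene sum changed by less than 1.5-fold. A gene whose sum holds 1 transcript lies on the dashed line of equal change by construction.

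GAPDH, the reference gene of the submitters' knockdown screen, had 2 transcripts called higher and none called lower. GAPDH-201 was at +2.95 (SE 0.382, adjusted p 3.94e-12 in the authors' deposited table) and GAPDH-211 at +2.20 (adjusted p 0.0276). The most abundant transcript, GAPDH-204, was at −0.66 (SE 0.259, base mean 23514, adjusted p 0.295), GAPDH-205 was at −5.61 (adjusted p 0.249), and the gene sum was +0.09 (SE 0.235), from 30889 to 32846. These transcripts share 13.8% to 20.9% of their windows with other genes, mainly GAPDHP1. Members of the fixed lists also had called transcripts beside sums that did not pass, among them FLNA-201 (−6.56, gene sum +0.24), MYC-202 (−7.71, gene sum +0.23), F3-202 (−8.88, gene sum −0.15), HYOU1-217 (+10.17, gene sum +0.09) and S100A4-203 (+9.31, gene sum −0.05). FOS-201 was at −8.61 beside a gene sum of −1.48 (SE 0.811).

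Summed over transcripts, a step chosen after the data had been seen, 54 of 12674 genes passed at an adjusted p under 0.05, 18 higher and 36 lower. The count depends on the null, with 664 when the statistics were scaled by their robust spread and 15 with standard errors larger by the square root of 2. Among those that fell were CASP3, the executioner caspase, SPTLC1, a subunit of the enzyme that starts sphingolipid synthesis, OSTM1, a lysosomal membrane protein, and the ubiquitin enzymes NEDD4 and UBA6. CASP3 (chr4:184627696–184649475, minus strand) fell from 1043 to 522 normalised reads (SE of the log2 change 0.158, adjusted p 2.27e-07). SPTLC1 fell from 2001 to 854 (−1.23, SE 0.226, adjusted p 3.95e-05). OSTM1 fell from 1430 to 614 (−1.22, SE 0.186, adjusted p 8.60e-08). NEDD4 fell by −0.68 (SE 0.136, adjusted p 3.20e-04) and UBA6 by −0.68 (SE 0.145, adjusted p 0.00101). SNU13, a protein of the U4 small nuclear ribonucleoprotein, fell from 1358 to 559 (−1.28, SE 0.163, adjusted p 1.86e-11). LYRM4, which serves iron–sulfur cluster assembly, was at −1.16 (SE 0.171, adjusted p 2.35e-08), and glutathione synthetase, GSS, at −2.12 (SE 0.447, adjusted p 8.82e-04). Smaller falls were those of the dehydrogenase-like HSDL1 (−0.87, SE 0.197), the carnosine methyltransferase CARNMT1 (−0.75, SE 0.115), the phosphatase inhibitor ARPP19 (−0.70, SE 0.130), the mitochondrial elongation factor TUFM (−0.57, SE 0.126), the SUMO protease SENP5 (−0.46, SE 0.0996) and IDH1 (−0.27, SE 0.0592).

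RASSF2, a Ras-association gene of chromosome 20 (chr20:4780023–4823645, minus strand), rose from 898 to 3650 (+2.02, SE 0.321, adjusted p 2.75e-07). NTN4, a laminin-related netrin of basement membranes, rose from 3472 to 7604 (+1.13, SE 0.245, adjusted p 0.00154). The tight-junction gene CLDN1 was at +1.51 (SE 0.334, adjusted p 0.00225), and SOAT1, which esterifies cholesterol, at +0.55 (SE 0.0951, adjusted p 5.81e-06). AGO2, the slicer of small-RNA silencing, rose by +0.38 (SE 0.0771, adjusted p 3.48e-04). The stromal receptor PDGFRA was at +0.34 (SE 0.0667, adjusted p 2.23e-04), and 22.8% of its windows are also found in AC058822.1, which makes it uncertain. RAB3B was at +0.27 (SE 0.0426, adjusted p 1.71e-07).

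Some sums passed with 1 arm near 0, such as PTPRK (−9.30), FBXW4 (−8.68), GPRASP2 (−8.12) and SHPK (+8.52). SHPK shares 73.3% of its windows with AC027796.3, which was at −6.69, and AC005520.1 (+7.04) shares 88.9% with ZNF410, so those values are uncertain. The readthrough gene DNAJC25-GNG10 (−1.38) shares 93.4% of its windows with GNG10, whose sum was at +0.02. The SE of a sum treats transcripts as independent, and transcripts that were not matched to a gene are not in it. Many of the sums that passed held 1 transcript, among them CASP3, OSTM1, RASSF2 and AGO2. In SPTLC1, NEDD4 and NTN4 the most abundant transcript made up 99.3%, 97.4% and 99.98% of the sum. Such sums add little or nothing to the authors' value for that transcript.

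**Figure D2:**
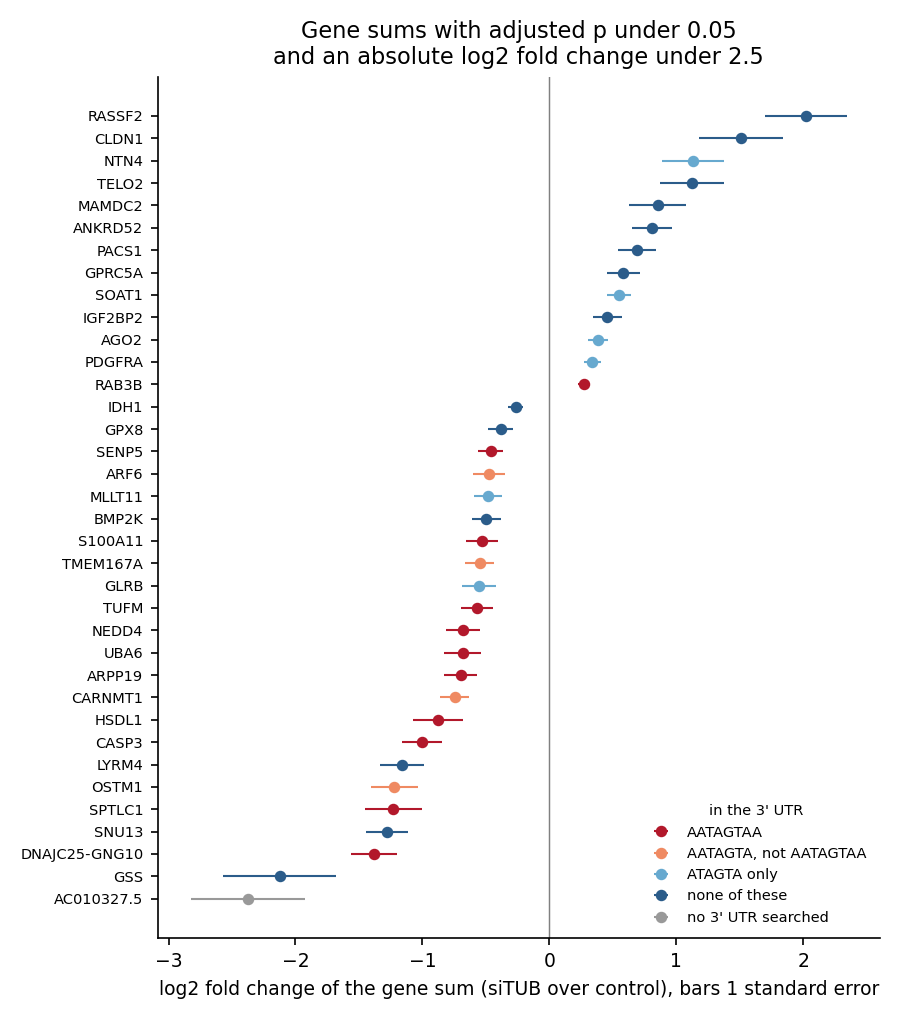
Points are gene sums with an adjusted p under 0.05 and an absolute log2 fold change under 2.5, TUB siRNA over control, and bars are 1 standard error. Colours give the sequence found in the 3′ UTR, and most genes with AATAGTAA or AATAGTA lie below 0, from CASP3 and SPTLC1 to SENP5, with RAB3B above 0.

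Genes with AATAGTA in the 3′ UTR were lower with TUB siRNA. Of all 15325 heptamers tested over 8903 genes, a search made after the data had been seen, AATAGTA had the lowest t, −21.4. Its 1188 genes were shifted by −0.13 (SE 0.00628) on the log2 scale. The next were ATAGTAA at −17.9 and TAGTAAA at −11.4, which overlap it, and the highest was GGGGAGA at +5.44. It ranked 1 among the genes of odd chromosomes, with a t of −16.7, and among those of even chromosomes, with −13.4, which are the same genes as in the search. The 450 genes with AATAGTAA had a median of −0.15, and 73.3% of them were below 0. The 738 genes with AATAGTA alone had a median of −0.04, and 57.9% were below 0. Of the 6277 genes with neither of these nor ATAGTA, 41.4% were below 0, with a median of +0.03. Genes with 1 site had a weighted mean of −0.09 and the 223 genes with more had −0.16. Unlike the ranking, these medians, shares and means of site classes were not adjusted for UTR length or GC content. Among the called sums with a searched UTR, 14 of 33 that fell held AATAGTA, against 1364 of all 11315 (12.1%). The 14 include CASP3, SPTLC1, OSTM1, CARNMT1, ARF6 and S100A11. They also include the readthrough gene DNAJC25-GNG10, which is uncertain, as it shares 93.4% of its windows with GNG10. Of those that rose it was 1 of 17, RAB3B. In coding sequences AATAGTA also ranked 1, with a t of −4.89 over 446 genes and an effect of −0.05, which is 0.351 of that in 3′ UTRs (SE 0.0736). TUB-202 holds AATAGTAA once, in its coding sequence, with AATAGTA at chr11:8096759–8096765. The sequence of the siRNA is not given in the labels. The ranking is across genes, which are not independent replicates.

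**Figure D3:**
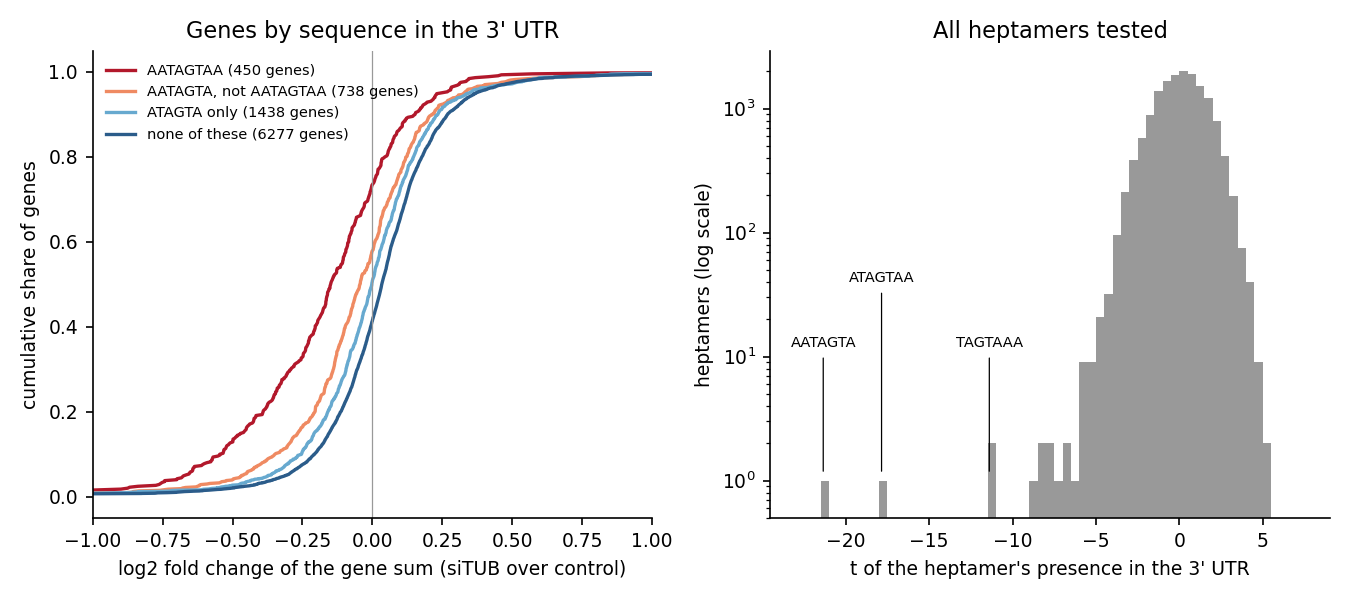
Left, cumulative share of genes by log2 fold change of the gene sum, TUB siRNA over control, for the sequence held in the 3′ UTR, where the curve of the 450 genes with AATAGTAA lies to the left. Right, number of heptamers (log axis) by t, with AATAGTA at −21.4 and the highest of all at +5.44.

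Of the 37 gene lists tested with cameraPR, 1 passed, the 13 messenger RNAs encoded by mitochondria, which were lower (adjusted p 1.48e-04, median log2 fold change −0.51). Of its members 1 was called over all transcripts, and 1 adjusted over the list alone, in both cases MT-ATP6 at −6.57, which shares 46.7% of its windows with MTATP6P1 and is uncertain. The other 12 had sums between −0.73 and −0.23. The list also passed in the rank version (adjusted p 4.72e-04), at a base mean of at least 100 (2.22e-04) and at a preset correlation of 0.05 (0.00421). Without MT-ATP6 the adjusted p of the list was 0.0670, with log2 fold changes in place of the Wald statistic it was 0.0821, and with a preset correlation of 0.5 it was 0.981, none of which passed.

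The list of decidualization, with 23 measured genes, showed no shift that passed (adjusted p 0.356), with 0 called and 0 adjusted over the list alone. PRL had 0 reads in all 3 of its listed transcripts, and IGFBP1 had a base mean of 0.549 and no adjusted p. These are the usual markers of a decidual cell, and these cells were harvested 48 h after transfection. FOXO1 was at −0.35 (SE 0.546), HOXA11 at −0.01 (SE 0.205), HAND2 at −0.23 (SE 0.153) and IL11 at −0.83 (SE 0.373), none of which passed. PGR, the progesterone receptor, had a sum of −0.55 (SE 0.256) that did not pass, and its 3′ UTR holds AATAGTAA. The 16 steroid receptor genes held 0 calls (adjusted p 0.948), with a median and a mean Wald statistic below 0 beside a test pointing up.

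Stromal identity, with 21 genes such as DCN (+0.02) and LUM (−0.28, SE 0.191), held 1 call, PDGFRA-201 at +0.35 (SE 0.0665, adjusted p 2.09e-05), and 1 adjusted over the list alone (list adjusted p 0.885). Contractile genes held 2 higher calls among 21, and 3 adjusted over the list alone (list adjusted p 0.187). These were MYOCD-203 and, in FLNA, which encodes filamin A, FLNA-203 at +3.87 beside a lower FLNA-201. MYOCD-203, from the myocardin coactivator of smooth-muscle genes, was at +1.27 (SE 0.355, adjusted p 0.0184), while its gene sum had an adjusted p of 0.0749. The 13 genes of small-RNA silencing held 1 call, AGO2, and 1 adjusted over the list alone (list adjusted p 0.240). The smooth muscle and pericyte list held 1 lower call among 13, and 1 higher and 1 lower adjusted over the list alone (list adjusted p 0.604). The amino-acid response list held 1 lower call among 26, ASNS-203 at −5.97 (gene sum −0.18, SE 1.36), which is uncertain, as 81.7% of its windows are also in AC079781.5, and 1 higher and 1 lower adjusted over the list alone (list adjusted p 0.604). Immediate early genes held 1 higher and 1 lower call among 29, MYC-207 and FOS-201, and the same numbers adjusted over the list alone (list adjusted p 0.604).

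Each of the S-phase, nuclear respiratory chain, ribosomal protein and housekeeping lists held 1 lower call, and 1 adjusted over the list alone. For the nuclear respiratory chain and housekeeping lists this call was the same transcript, SDHA-201. In the order above, the adjusted p-values of the lists were 0.885, 0.885, 0.604 and 0.356. The housekeeping list had a median log2 change above 0 beside a test pointing down. Among all transcripts of their members, SDHA-201 at −8.63, RPS3-209 at −5.48, RPL7-202 at +6.66 and RPS7-211 at +9.74 were called. All are uncertain, as windows of each are also in other genes, with 22.3% for SDHA-201, 54.2% for RPL7-202 and 65.0% for RPS7-211, and none of their gene sums passed (RPL7 +0.18, SE 1.56; RPS7 +0.21, SE 1.04). Every other tested list held 0 calls over all transcripts and 0 adjusted over the list alone for the most abundant transcript of each gene. The lowest of their adjusted p-values were 0.0528 for Gq and phosphoinositide signalling, with 28 genes and a test pointing up, 0.0666 for the 24 genes of cholesterol synthesis, pointing down, and 0.0898 for the 29 interferon genes, pointing down. TGF-β and BMP genes (30) and insulin and IGF genes (21) each had 0.145. Cilium and intraflagellar transport, with 42 genes, had 0.411, Hedgehog, with 15, had 0.223, and Wnt, with 24, had 0.590. The lists of mitosis, matrix proteases, tubulins and engulfment each had 0.885, collagens had 0.612, and YAP targets had 0.210. The others, from histones and p53 targets to heat shock and neuronal genes, lay between 0.153 and 0.885. In transcripts other than the most abundant one, IFT74-204 (+8.62), IFT43-212 (+2.14), TCTN1-223 (+0.74), KIF23-202 (−7.85) and DLC1-210 (+5.61) were among those called in the authors' deposited table. In that order, their gene sums were −0.42 (SE 1.58), −0.05, +0.05, +0.07 and −0.07, and none of these sums passed.

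The endothelial, leukocyte and tubby lists had 3, 2 and 3 measured members and were not tested. With every transcript of a member counted, the endothelial list passed at 0.0152 over 7 transcripts, of which FLT1-207 was called at +10.39, beside a gene sum of +1.01 (SE 0.471) that did not pass. Transcripts of the same gene, which are not independent, counted there as separate members of a list with 3 measured genes. This pass is therefore no test over separate genes.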

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

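The settings on gene sums, on all transcripts in the list test, on the heptamer, without MT-ATP6, without called transcripts of little-changed genes and at a correlation of 0.5 were chosen after the data were seen, the others before. For siTUB against control, the 569 called transcripts became 329 at a base mean of at least 100 (312 shared), 917 with an empirical null, 261 with standard errors larger by the square root of 2, and 112 without called transcripts of genes changed by less than 1.5-fold. Gene sums gave 54. Centring on the median gave 570 (233 higher, 337 lower). Of the gene sums, 15 passed with standard errors larger by the square root of 2, and 664 when scaled by their robust spread. Of the lists, 1 passed cameraPR, against 0 with log2 fold changes ranked, 6 in the rank version, 9 on gene sums, 2 on all transcripts, 4 without genes holding the heptamer, 0 without MT-ATP6 and 0 at a correlation of 0.5, all by cameraPR. On all transcripts, those of the same gene counted as separate members although they are not independent. TUB-202 had an adjusted p of 0.0695 when centred, 1.00 with the larger errors, 0.266 as a gene sum and 0.00792 with an empirical null, where it passed. AATAGTA ranked 1 under all settings, with t from −22.7 to −14.4. At a tolerance of 1 in 100 the number of libraries read from the table was 4. No paired analysis was possible because the table holds no values per library. For the same reason, other size factors or another count model, unfiltered counts, TUB siRNA replicate 1, leaving out each replicate, run a or run b alone and an estimated correlation were not run. For base means up to 100, the counts solved in the 5 unnamed libraries would have allowed leaving out 1 library at a time, which was not done.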

Other observations

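On gene sums, a setting chosen after the data were seen, 9 lists passed cameraPR in place of 1, among them 2 of lipid synthesis, and why more passed was not tested. Cholesterol synthesis was lower (adjusted p 0.00129), with a median log2 change of −0.22 and CYP51A1 at −0.22 (SE 0.0943), MSMO1 at −0.31 and HSD17B7 at −0.87 (SE 0.425). Lipogenesis was lower as well (0.0269). Gq and phosphoinositide signalling, the pathway that frees tubby from the membrane, was higher (0.0102), with a median of +0.12, GNA11 at +0.14 and INPP5A at +0.36. The interferon list was lower (0.0108), with a median of −0.17 and STAT1 at −0.31. Insulin and IGF (0.0319), Hedgehog (0.0345), p53 (0.0465) and YAP (0.0465) were higher, and mitochondrial RNAs lower (1.15e-08). No single member of the cholesterol, Gq or interferon lists passed, and an estimated correlation could not be used. Without genes that hold AATAGTA the cholesterol, Gq and interferon lists each stood at 0.0463 in the transcript test. With all genes that test gave them 0.435, 0.435 and 0.459 at a preset correlation of 0.05, and 0.895, 0.400 and 0.685 with log2 fold changes ranked.

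Genes with AATAGTA in their 3′ UTR, among them CASP3, SPTLC1, OSTM1 and NEDD4, were lower with TUB siRNA, and all the tests of this pattern came after the search had shown it, those of the siRNA seed and of lower TUB itself last. Heptamers of the same composition that share no hexamer with AATAGTAA reached at most 0.294 of its t, which argues against base composition as the whole cause. The t in coding sequences was 0.229 of that in UTRs and the effect 0.351 (SE 0.0736), which argues against a property of the whole transcript, although the heptamer ranked 1 there as well. Off-target silencing through the siRNA seed is a candidate explanation that stays open, since TUB-202 holds AATAGTAA, as 0.102 of 4714 transcripts of like length do. Genes with AATAGTAA lay lower than those with AATAGTA alone (−0.11, SE 0.0163), without adjustment for UTR length or GC content. AATAGTAA joins the 2 lowest heptamers of the search over these same genes, AATAGTA and ATAGTAA, so that difference is no separate support. The labels give no siRNA sequence, so AATAGTA is not known to match the seed of the siRNA. Lower TUB itself cannot be told apart from off-target silencing. The labels hold 1 group of siRNA against TUB and do not say whether that is 1 siRNA or a pool.

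Of the 165 called transcripts with base means of 20 to 100, 105 were on-off, with 0 reads in some libraries and at least 10 in each of the others, and the test against whole-gene change was chosen after the result was seen. Read assignment between transcripts that varies from library to library is a candidate explanation, since 107 on-off transcripts of these base means, called or not, followed the real split of the 5 libraries and up to 120 followed another of the 10 splits. For on-off transcripts of these base means, a regulated change of transcript use after TUB siRNA is not favoured as their main source. The real split held 0.892 of the number in the highest other split. The other 9 splits ran from 71 to 120, with a median of 107. This count cannot exclude some regulated transcripts among the 107. It covered neither graded changes nor more abundant transcripts, such as those of XPO6 and TCEAL9. A change of the whole gene's level accounts for few of the called transcripts at an absolute log2 fold change of 5 or beyond. Of these, a share of 0.146 had a gene sum that moved at least 1.5-fold the same way. That share includes genes with 1 transcript, such as MT-ATP6, whose sum is the transcript's own value. The 10 splits are too few for a share under 0.05, and the libraries have no names.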
